A study of Mus musculus with 48 samples.

How the data were processed

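Gene expression was measured with bead arrays in primary calvarial osteoblasts, the bone-forming cells of the mouse skull, from wild-type mice (WT) and from mice without a functional oncostatin M receptor gene Osmr (KO), on a C57BL/6 background. The cells were differentiated for 17 days and then left untreated (control) or given murine oncostatin M (mOSM), human oncostatin M (hOSM) or leukemia inhibitory factor (called mLIF here, after the sample labels) at 10 ng/ml for 1 h or 6 h. This makes 16 groups of 3 arrays, 48 arrays on 8 beadchips. The labels disagree on the source of the LIF, which the design text and the sample titles call mouse and the treatment protocol calls human. The design text describes 3 thawing occasions, while the labels give 2 thawing days, with replicates 1 and 2 on the first and replicate 3 on the second. Whether the cultures of a genotype came from separate animals is not stated. The p-values measure the spread between these samples, pooled over all 16 groups, and may not cover that between animals.

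The deposited signal file holds a bead intensity per probe and array on a linear scale, not normalized between arrays, which the authors exported from BeadStudio. It also holds the detection p-value of each probe against the negative control probes of its array, as deposited by the authors. A second deposited table holds values on the log2 scale that the authors had normalized between arrays, and their processing notes name BeadStudio and limma without versions or settings. The signal file has 46255 lines, of which 18 repeat an earlier probe, leaving 46237 probes. Of these, 45281 are in the normalized table and 956 occur in the signal file alone. The steps of the detection p-values imply 936 negative control probes. Median signals ran from 116.3 to 169.8 between arrays, and 14231 to 16767 probes per array had a detection p under 0.01. The number of arrays, 3 per group, limits the precision of each value.

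The signals were corrected for background with the normal-exponential model of limma (neqc, with negative controls inferred from the detection p-values and an offset of 16), quantile normalized and put on the log2 scale. The result differed from the deposited log2 values by at most 0.03376. Gene names came from the annotation supplied with the series: 34885 probes had 1 symbol, 18 had several and 10378 of the normalized table had none. Symbols were compared through Entrez identifiers with a RefSeq gene table, where 34807 probes matched and 0 symbols changed. The files do not name a genome build, so no positions are given. Probes with a detection p under 0.01 on at least 3 of the 48 arrays were kept (16799 probes), and for the 4119 genes with more than 1 such probe the probe with the brightest mean was used. This left 10739 genes.

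A linear model with 16 group means was fitted to each gene with limma 3.58.1 in R 4.3.3, with the packages data.table (1.17.8) and jsonlite (2.0.0) for reading the files, and with moderated statistics on 32 residual degrees of freedom before moderation. P-values were adjusted by Benjamini and Hochberg within each comparison, and an adjusted p under 0.05 counted as passing. The comparisons were each ligand against the control of its genotype and time, the ligands against each other, the difference of each ligand effect between KO and WT (the interaction), KO against WT controls, 6 h against 1 h controls and, for Osmr, all KO against all WT arrays. The change of a ligand effect from 1 h to 6 h was taken from the same model.

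Before the data were examined, 20 gene lists were fixed. Those described here cover STAT3 targets and feedback, immediate early genes, gp130 family receptors and ligands, osteoblast genes, osteocyte genes, osteoclast-regulating factors, chemokines and inflammatory mediators, acute phase and complement, Wnt pathway antagonists and targets, matrix proteases and inhibitors, TGF-beta and BMP pathway genes, hypoxia and glycolysis genes, heat shock and unfolded protein response, cell cycle genes, and adipocyte, macrophage and osteoclast, endothelial, chondrocyte and muscle markers. Some genes are on more than 1 list. Lists were tested against all other genes with camera at its preset correlation between genes of 0.01 and again with an estimated correlation, and p-values were adjusted over the lists of a comparison. Counts of list members are given over all genes tested and, where stated, also adjusted over the list alone. The rule for naming genes was fixed at the same time: 20 genes of this pathway and of bone cells in every comparison, the 10 genes with the largest change among those past the threshold whose groups do not overlap (6 for interactions and for ligands against each other), and up to 4 members of each list with the largest change past the threshold. The text names a part of these. Of the 20 genes, Sost, with 1 probe, was detected on 0 of 48 arrays and so was not tested. Runx2, on the osteoblast list, has no named probe in the annotation.

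Alternatives chosen at that time were the replicate number or the beadchip as a term of the model, no detection filter, the deposited log2 values, no background correction, median scaling in place of quantile normalization, a model of the compared groups alone, and leaving out each array in turn. Further alternatives were chosen after the data were examined: a term for the culture (genotype and replicate number together, 6 cultures of 8 arrays), the culture as a random effect for comparisons between genotypes, leaving out the KO replicate 3 culture, the first thawing day alone and, for named genes, raising arrays not above background to the lowest signal above it on the same array (the floor). The list test of the 6 h against 1 h controls was also added then. The scripts were tested on simulated data in which 200 of 10739 genes were changed in each of 10 runs. For mOSM in WT at 6 h the group-mean model recovered 13.3% of the 1.5-fold, 51.3% of the 2-fold and 89.7% of the 4-fold changes, with 1% of the calls false. With the culture term the shares were 39.3%, 82.8% and 99.2%, with 4.6% false. For the mOSM interaction at 6 h the group-mean model recovered 2.2%, 21.8% and 72.6%. In the real data 2956 and 1042 genes passed in these comparisons, far more than the 200 changed here. The adjustment of p-values depends on how many genes change, so these shares need not hold for the real comparisons. A shifted list was called in 10 of 10 runs and 0 of 190 unshifted lists were. The simulated noise was independent between genes and the lists were random draws. These runs thus do not give the rate of false calls for lists whose genes vary together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.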

Results

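The study measured gene expression on 48 bead arrays from WT and KO osteoblast cultures given mOSM, hOSM or mLIF, or left as controls, for 1 h or 6 h, with 3 arrays in each of the 16 groups. Per the design text, hOSM and LIF act in mouse cells through the LIF receptor (LIFR), while mOSM can act through both the OSM receptor (OSMR) and LIFR, so that the ligands and genotypes separate the receptors. Changes are log2 differences ± SE (n = 3 arrays per group unless stated), with limma's adjusted p. All 147 ligand effects named here as risen or fallen had that direction in each of the 3 cultures of their genotype. This was largely fixed by the choice of genes, which passed the threshold on these same arrays. Leaving out any single array of the compared groups left each named call in place unless stated. For 33 of the differences between groups named here as passing, a group had only part of its arrays above background. Raising its other arrays to the floor brought these differences toward 0 by at most 0.47 and turned 0 of them.

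The receptor gene itself separated the genotypes. Osmr, which encodes the receptor chain that binds OSM, averaged 7.36 ± 0.74 (SD, n = 24) in KO and 10.68 ± 0.80 (SD, n = 24) in WT arrays on the log2 scale. It was 9.953-fold lower in KO (difference −3.32 ± 0.16, adjusted p = 4.2e-17; with the culture as a random effect SE 0.26, adjusted p = 4.9e-11). The highest KO array, at 8.75, was below the lowest WT array, at 9.51. Over the 3 KO and 3 WT culture means the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. The probe was above background on all 24 KO arrays, and the files do not say where it lies relative to the deleted part of the gene.

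**Figure D1:**
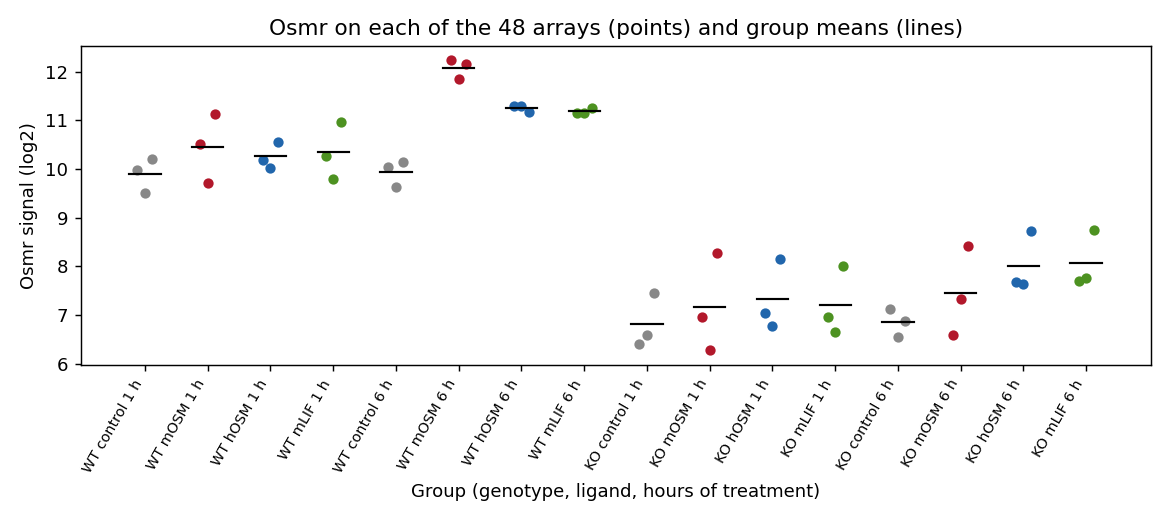
Osmr signal (log2) on each array (points) and group means (lines) by genotype, ligand and hours of treatment, n = 3 arrays per group. All 24 KO arrays lie at or below 8.75 and all 24 WT arrays at or above 9.51.

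The cultures differed from each other beyond their treatment. After removal of the group means, arrays of the same genotype and replicate number correlated with a mean r of 0.659 (lowest 0.302). Arrays of the same genotype with another number had a mean of −0.303. The closest array of another group belonged to the same culture for 48 of 48 arrays. A replicate number shared across genotypes gave a mean r of −0.001. A model with a culture term, chosen after the data were examined, removes this spread, so its p-values rest on the spread within cultures. Its values are given where they change the call of a gene or list described here. They are also given where they move the number of genes passing in a comparison by more than 1.5 times. Counts of list members under this term are given for some lists only. The first principal component (29.6% of the variance) set the KO replicate 3 culture, with a mean of 60.7, apart from the other cultures, with means of −17.7 to −0.1.

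**Figure D2:**
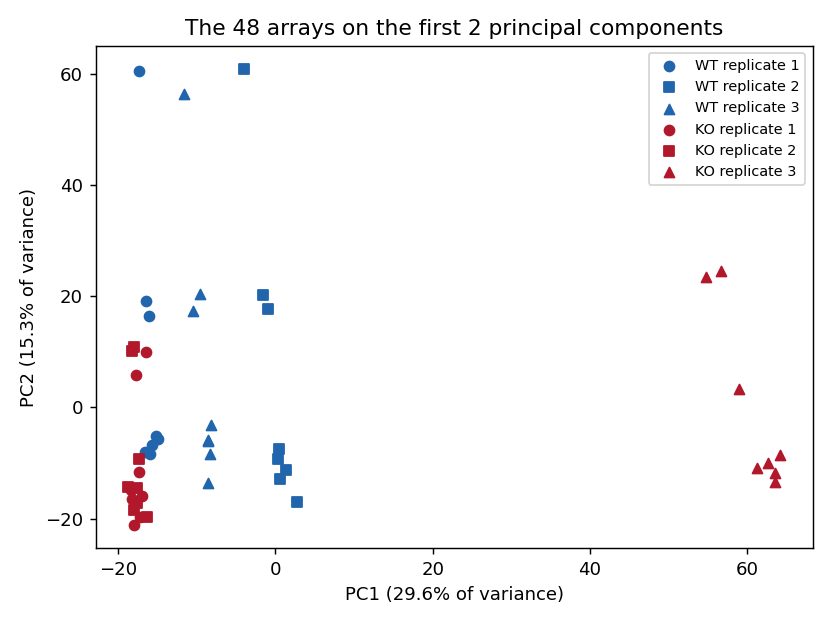
The 48 arrays on the first 2 principal components (29.6% and 15.3% of the variance), by genotype (color) and replicate number (shape). The 8 arrays of KO replicate 3 lie between 54.79 and 64.14 on PC1, to the right of every other array.

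In WT cultures, 6 h of mOSM raised Socs3, Ccl2, Ccl7 and Tnfsf11 and lowered Sp7 and Pparg. Socs3, a feedback inhibitor of gp130 signalling, rose by 4.97 ± 0.34 (31.4-fold, adjusted p = 8.3e-13). Ccl2 and Ccl7, chemokines that attract monocytes, rose by 5.54 ± 0.57 (adjusted p = 3.5e-09, 5.29 with arrays raised to the floor) and 5.12 ± 0.57 (adjusted p = 1.7e-08). Tnfsf11, which encodes RANKL, the factor that drives osteoclast formation, rose by 4.74 ± 0.76 (adjusted p = 1.1e-05, 4.57 with arrays raised to the floor). Sp7, a transcription factor required for osteoblast formation, fell by 2.62 ± 0.49 (adjusted p = 9.3e-05), and Pparg, the main regulator of fat cell formation, fell by 2.44 ± 0.50 (adjusted p = 0.00031).

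In all, 2956 of 10739 genes passed, 1283 higher and 1673 lower, of which 616 were higher and 648 lower by more than 2-fold. The culture term gave 4858, 1904 higher and 2954 lower, and all 2956 kept their call. Under median scaling, which shifted the median of all genes by −0.187 (−0.084 with quantile normalization), 32.5% of the called genes were higher in place of 43.4%. The shifts by median scaling reached 0.305 at most over all comparisons, for the mLIF interaction at 6 h.

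Of the 16 measured STAT3 targets and feedback genes, 12 rose with mOSM at 6 h, 0 fell and 4 did not pass (12 and 0 adjusted over the list alone; camera adjusted p = 1.7e-10, 0.0061 with an estimated correlation). Besides Socs3, they included Il4ra, a receptor chain for interleukin 4, which was at least 13.7-fold higher (4.57 ± 0.45, adjusted p = 1.7e-09) since no control array was above background. Others were the NF-kappaB cofactor Bcl3 (3.63 ± 0.51, 3.40 with arrays raised to the floor) and the AP-1 gene Junb (3.49 ± 0.42, adjusted p = 6.9e-08). Stat3 itself, the transcription factor that gp130 activates, rose by 1.22 ± 0.23 (adjusted p = 9.8e-05) and Cebpb, a transcription factor of osteoblasts and fat cells, by 1.31 ± 0.22 (adjusted p = 2.9e-05). Among 25 immediate early genes, 12 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 2.1e-05, 0.029 with an estimated correlation and 0.082 with an estimated correlation and the culture term). Fos (2.52 ± 0.65), Egr2 (2.38 ± 0.29) and Myc (2.26 ± 0.43, 1.79 with arrays raised to the floor), transcription factors of the growth response, were among those that rose. The controls of Junb, Fos and Egr2 were themselves lower at 6 h than at 1 h, as described below. Their rises at 6 h are thus measured from a lowered control level.

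The receptor components changed too. Of 11 gp130 family receptors and ligands, 5 rose and 1 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.18). Il6st, the shared gp130 chain, rose by 2.42 ± 0.38 (adjusted p = 6.8e-06), Osmr by 2.15 ± 0.45 (adjusted p = 4e-04). Il6, a cytokine that also signals through gp130, was at least 4.52-fold higher (3.20 ± 0.44, adjusted p = 7.1e-07). Ctf1, the gp130 ligand cardiotrophin 1, fell by 1.88 ± 0.25 (adjusted p = 5.1e-07). Lifr did not pass (−0.56 ± 0.29, adjusted p = 0.16), while the culture term gave adjusted p = 0.038.

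Of 17 chemokines and inflammatory mediators, 9 rose and 0 fell (11 and 0 adjusted over the list alone; camera adjusted p = 4.2e-06, 0.014 with an estimated correlation). Among them were Cxcl9 (4.44 ± 0.57) and Cxcl1 (4.32 ± 1.03, adjusted p = 0.0015), which attract T cells and neutrophils. Other genes that rose included the ubiquitin-like Isg15 (3.91 ± 0.71, adjusted p = 5.6e-05) and the GTPases Gbp2 (3.10 ± 0.55) and Igtp (3.08 ± 0.64). Ifi205 was at least 46.9-fold higher (6.16 ± 0.98, adjusted p = 9.7e-06). Of 14 acute phase and complement genes, 2 rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.072). Of them, 6 rose with the culture term (camera adjusted p = 0.014, or adjusted p = 0.08 with an estimated correlation). Serpina3n, a protease inhibitor of the acute phase, rose by 3.66 ± 0.46 (adjusted p = 1.8e-07), and its relative Serpina3f was at least 20.5-fold higher. Mt2, a metal-binding metallothionein, rose by 5.13 ± 0.64 (adjusted p = 1.6e-07), and Mcoln2, a lysosomal ion channel, by 5.10 ± 0.75 (5.09 and 4.81 with arrays raised to the floor).

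Genes that regulate bone cells moved in both directions. Of 14 osteoclast-regulating factors, 5 rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.033), and the list was not past the threshold with an estimated correlation (adjusted p = 0.16 with an estimated correlation). Sp7 was the 1 of 11 osteoblast genes that passed (0 rose and 1 fell, also adjusted over the list alone; camera adjusted p = 0.38). With the culture term 6 osteoblast genes fell. Among them were Alpl, the mineralization enzyme alkaline phosphatase (−0.73 ± 0.49, adjusted p = 0.29, or 0.00036 with the culture term), and Bglap, which encodes osteocalcin (−1.13 ± 1.87, adjusted p = 0.72, or 0.019). Pth1r, the parathyroid hormone receptor, had −0.64 ± 0.43 (adjusted p = 0.3, or 0.0015). Col1a1, the main bone collagen chain, differed by −0.12 ± 0.16 (adjusted p = 0.64). Of 10 osteocyte genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.19). The risen ones were Cd44 (1.43 ± 0.32), a receptor for hyaluronan, Ank (1.10 ± 0.15), a pyrophosphate exporter, and the membrane glycoprotein Pdpn (0.91 ± 0.21). The osteocyte genes Dmp1 (0.18 ± 0.73, above background on 0 of 6 arrays) and Mepe (0.27 ± 0.24, on 2 of 6) were near the lower limit of the arrays.

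Wnt and BMP pathway genes mostly fell among those that passed. Of 15 Wnt pathway antagonists and targets, 1 rose and 6 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.064, or 0.041 with the culture term and adjusted p = 0.08 with an estimated correlation as well). Nkd1, an inhibitor of Wnt signalling that Wnt itself induces, was at least 5.68-fold lower (−3.29 ± 0.23, adjusted p = 1.4e-12). The Wnt-enhancing ligand Rspo2 (−1.82 ± 0.29), its receptor Lgr5 (−1.89 ± 0.49) and the Wnt target Ccn4 (−1.38 ± 0.22) fell as well. Of 16 TGF-beta and BMP pathway genes, 2 rose and 5 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.28). Bmp4, a bone-inducing ligand, fell by 2.09 ± 0.46, the BMP target Hey1 fell by 1.95 ± 0.35 and Tgfb3 fell by 1.60 ± 0.22. The matrix protein gene Tgfbi rose by 1.88 ± 0.24. Of 18 matrix proteases and inhibitors, 7 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.21). Among the risen were the proteases Mmp3 (3.71 ± 0.67) and Adamts4 (2.24 ± 0.31) and the urokinase receptor Plaur (2.79 ± 0.48).

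Of 10 hypoxia and glycolysis genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.033, adjusted p = 0.05 with an estimated correlation and 0.061 with the culture term). Hif1a, the oxygen-regulated transcription factor, rose by 1.69 ± 0.28 and the secreted lipase inhibitor Angptl4 by 2.44 ± 0.39. Of 16 genes of the heat shock and unfolded protein response, 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.14). Xbp1, a regulator of the unfolded protein response, rose by 1.13 ± 0.13, and the chaperone Hspa1a was at least 1.71-fold lower (−1.68 ± 0.30). Of 12 adipocyte markers, 0 rose and 2 fell, Pparg and Dgat2, a triglyceride-making enzyme (−2.50 ± 0.62), with the same count adjusted over the list alone (camera adjusted p = 0.14). Of these markers, 7 fell with the culture term (camera adjusted p = 0.0028, or adjusted p = 0.082 with an estimated correlation). Of 15 cell cycle genes, 0 passed in limma, also adjusted over the list alone (camera adjusted p = 0.92), while 4 rose and 8 fell with the culture term. Of 10 chondrocyte markers, 1 fell, the cartilage regulator Sox9 (−1.42 ± 0.25; camera adjusted p = 0.75). Of the markers of other cells, 1 of 12 macrophage and osteoclast markers rose (camera adjusted p = 0.57). In limma 0 of 5 endothelial (camera adjusted p = 0.92) and 0 of 4 muscle markers (camera adjusted p = 0.92) passed, with the same counts adjusted over each list alone. Across the 10739 genes, 3967 had an unadjusted p under 0.05.

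After 1 h of mOSM in WT cultures the response was narrower and made up mostly of genes that rose. Pde4b, which breaks down cyclic AMP, rose by 4.60 ± 0.55 (24.3-fold, adjusted p = 8.8e-07), Socs3 by 3.46 ± 0.34 (11.0-fold, adjusted p = 1.8e-08), and Ccl2 and Ccl7 by 3.80 ± 0.57 and 3.53 ± 0.57. Irf1, a transcription factor of the interferon response, rose by 2.93 ± 0.25 (7.62-fold, adjusted p = 8.5e-10). Id1, a BMP target that inhibits differentiation, fell by 2.63 ± 0.31 (6.20-fold, adjusted p = 8.8e-07).

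In all, 80 genes passed, 71 higher and 9 lower, and 176 did so with the culture term (151 and 25). Without WT mOSM 1 h replicate 3 the count was 46. A beadchip term ended the calls of Junb, Btg2, Ccl7, Cxcl10 and Serpina3f (adjusted p 0.097 to 0.24). The model of the compared groups alone ended those of Ccl2, Cxcl10, Il6, Has1 and Adamts4 (adjusted p 0.05 to 0.11), and no background correction that of Serpina3f (adjusted p = 0.051).

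Of 16 STAT3 targets and feedback genes, 5 rose and 1 fell at 1 h of mOSM (9 and 1 adjusted over the list alone; camera adjusted p = 3.4e-23, 8.8e-06 with an estimated correlation). They included the feedback inhibitors Socs1 (2.85 ± 0.30, adjusted p = 1.3e-07) and Cish (2.88 ± 0.34, adjusted p = 7.3e-07) as well as Junb (2.46 ± 0.42). Of 25 immediate early genes, 7 rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 1.6e-20, 7.7e-06 with an estimated correlation). One was Btg2, an inhibitor of cell division (2.81 ± 0.48, adjusted p = 0.00053). Of 17 chemokines and inflammatory mediators, 4 rose (5 adjusted over the list alone; camera adjusted p = 1.5e-14, 2.6e-05 with an estimated correlation), with Cxcl9 up by 3.43 ± 0.57 and Cxcl10 at least 10.2-fold higher. Rnf213, an interferon-inducible ubiquitin ligase, was at least 4.76-fold higher (3.27 ± 0.28, adjusted p = 8.5e-10). Of 14 osteoclast-regulating factors, 3 rose, Ccl2, Ccl7 and Il6 (2.64 ± 0.44, adjusted p = 0.00033), and 3 did so adjusted over the list alone (camera adjusted p = 1.7e-05, 0.0074 with an estimated correlation). Adamts4 (2.63 ± 0.31, adjusted p = 8.8e-07) was the 1 of 18 matrix genes that rose (camera adjusted p = 0.019, adjusted p = 0.021 with an estimated correlation and 0.056 with an estimated correlation and the culture term). Of 10 hypoxia and glycolysis genes 1 rose (camera adjusted p = 0.02, adjusted p = 0.026 with an estimated correlation and 0.069 with an estimated correlation and the culture term). The hyaluronan synthase Has1 was at least 6.43-fold and Serpina3f at least 10.1-fold higher. The heat shock list had 1 risen member, the chaperone Dnajb1 (1.39 ± 0.15, adjusted p = 1.5e-07), and camera adjusted p = 0.028 (adjusted p = 0.37 with an estimated correlation, camera adjusted p = 0.056 with the culture term). Tnfsf11 (1.56 ± 0.76, adjusted p = 1), Cebpb (0.85 ± 0.22, adjusted p = 0.07) and Fos (2.05 ± 0.65, adjusted p = 0.27) did not pass. With the culture term they did (adjusted p = 0.00089, 0.00028 and 0.046), and Cebpb also passed without WT control 1 h replicate 3 (1.03).

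The effect of mOSM in WT changed with time for 1392 genes, 595 toward higher and 797 toward lower values at 6 h. The culture term gave 3267 (1237 and 2030). The Irf1 response was lower at 6 h than at 1 h (−2.23 ± 0.35, adjusted p = 4.3e-05), and so was that of Socs1 (adjusted p = 0.0027), for which no 6 h control array in WT was above background. The responses of Socs3 (1.51 ± 0.48, adjusted p = 0.031) and Cebpd, a transcription factor that STAT3 induces (1.62 ± 0.31, adjusted p = 0.00036), were higher at 6 h. The fall of Id1 with mOSM was smaller at 6 h than at 1 h (time difference 1.70 ± 0.44, adjusted p = 0.0081). For Socs3 and Id1 the WT controls were themselves lower at 6 h, at 8.81 against 10.92 and at 9.52 against 10.89, while with mOSM Socs3 was at 13.78 against 14.38 and Id1 at 8.59 against 8.26. The larger rise of Socs3 and the smaller fall of Id1 thus go with the lower control level. With hOSM and mLIF the Irf1 response was lower at 6 h in WT (−2.66 ± 0.35 and −2.57 ± 0.35) and in KO cultures (−2.57 ± 0.35 and −2.43 ± 0.35). Adjusted p was 0.00029 or less in all 4.

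**Figure D3:**
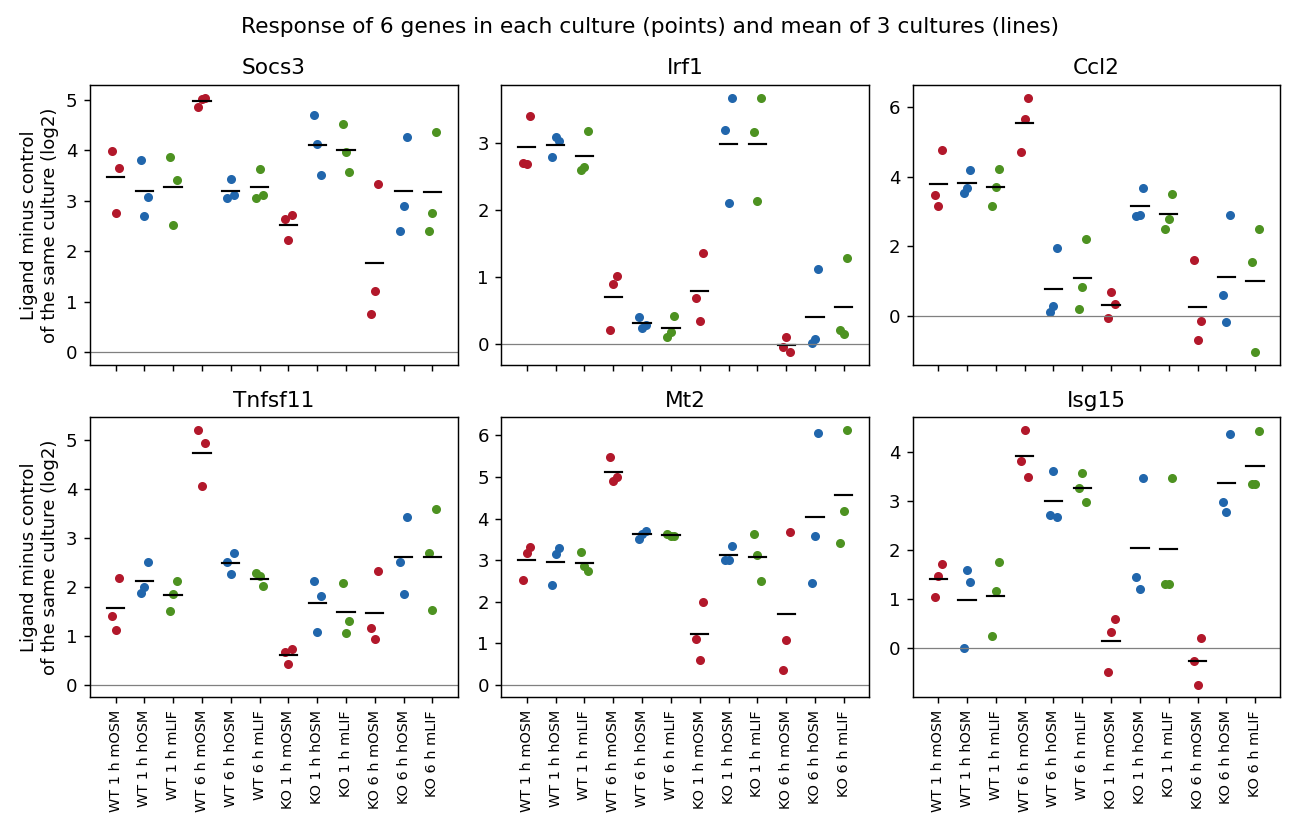
Log2 difference of each ligand from the control of the same culture for 6 genes, as points for the 3 cultures and lines for their means, by genotype, hours and ligand (mOSM red, hOSM blue, mLIF green). Tnfsf11 averages 4.74 for mOSM in WT at 6 h and Irf1 averages 0.80 for mOSM against 2.98 for hOSM in KO at 1 h.

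The comparison of hOSM and mLIF with controls asked what ligands of LIFR do. At 1 h in WT cultures, hOSM and mLIF raised early genes that mOSM also raised. Socs3 rose by 3.19 ± 0.34 with hOSM (adjusted p = 1.5e-07) and by 3.27 ± 0.34 with mLIF (adjusted p = 7.8e-08). Socs1 rose by 3.16 ± 0.30 and 2.99 ± 0.30, Cish by 2.98 ± 0.34 and 3.00 ± 0.34. Irf1 rose by 2.97 ± 0.25 (adjusted p = 8.4e-10) and 2.81 ± 0.25 (adjusted p = 3.9e-09). Ccl2 rose by 3.80 ± 0.57 and 3.70 ± 0.57, Ccl7 by 3.48 ± 0.57 and 3.46 ± 0.57, Pde4b by 3.30 ± 0.55 and 3.76 ± 0.55 and Adamts4 by 2.48 ± 0.31 and 2.44 ± 0.31. Id1 fell by 2.06 ± 0.31 (adjusted p = 0.00014) and 2.22 ± 0.31 (adjusted p = 3.5e-05). With hOSM, Il6 rose by 2.59 ± 0.44, the interferon-inducible Gm4841 was at least 7.12-fold and Serpina3f at least 9.46-fold higher, and with mLIF Dnajb1 rose by 0.98 ± 0.15 (adjusted p = 0.00014).

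With hOSM 50 genes passed, 45 higher and 5 lower, and with mLIF 67, 61 higher and 6 lower. The culture term gave 156 (131 higher and 25 lower) and 182 (155 and 27). Leaving out single arrays gave 32 (WT control 1 h replicate 2) and 33 (hOSM replicate 3) for hOSM. For mLIF they gave 32 (WT control replicate 1), 38 (WT control replicate 2), 39 (WT control replicate 3) and 36 (mLIF replicate 1 and also mLIF replicate 3). The model of the compared groups ended the calls of Pde4b with both ligands (adjusted p 0.17 and 0.09) and of Gm4841 (adjusted p = 0.056). The beadchip term ended those of Ccl2 (adjusted p = 0.07), Ccl7 (adjusted p = 0.18) and Dnajb1 (adjusted p = 0.061) with mLIF, and no background correction that of Serpina3f with hOSM (adjusted p = 0.11).

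The STAT3 list had 5 risen and 0 fallen members of 16 with hOSM (10 and 0 adjusted over the list alone; camera adjusted p = 6e-36, 2.4e-07 with an estimated correlation). It had 6 and 0 with mLIF (9 and 1 adjusted over the list alone; camera adjusted p = 4.4e-23, 1.9e-05 with an estimated correlation). Chemokines rose in 3 and 4 of 17 cases (camera adjusted p = 2.6e-13 and 3e-11, 6.7e-05 and 0.00025 with an estimated correlation). Immediate early genes rose in 2 and 3 of 25 (camera adjusted p = 7.2e-06 and 5.1e-08, 0.016 and 0.0039 with an estimated correlation). With the culture term as well as an estimated correlation, the list was not past the threshold for hOSM (adjusted p = 0.061). The hypoxia list passed with hOSM, with 0 of 10 genes past the threshold in limma (camera adjusted p = 0.014, 0.023 with an estimated correlation), and not with an estimated correlation and the culture term (adjusted p = 0.061). Osteoclast-regulating factors rose in 3 of 14 with both (camera adjusted p = 4.9e-07 and 3.3e-05, 0.0021 and 0.0097 with an estimated correlation). The heat shock list passed with hOSM (camera adjusted p = 0.014) but not with an estimated correlation (adjusted p = 0.32 with an estimated correlation). Tnfsf11 did not pass with hOSM (2.13 ± 0.76, adjusted p = 0.6) or mLIF (1.83 ± 0.76, adjusted p = 0.82). It passed with the culture term (adjusted p = 1.1e-05 and 0.00012) and in the model of the compared groups (adjusted p = 0.012 and 0.023). Cebpb (0.80 ± 0.22, adjusted p = 0.15, and 0.71 ± 0.22, adjusted p = 0.29) passed with the culture term (adjusted p = 0.00092 and 0.0034).

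At 6 h in WT cultures, hOSM and mLIF raised Mt2, Socs3, Cxcl9 and Serpina3n. Mt2 rose by 3.62 ± 0.64 with hOSM (adjusted p = 0.0016) and 3.59 ± 0.64 with mLIF (adjusted p = 0.0021). Socs3 rose by 3.20 ± 0.34 (adjusted p = 1.4e-07) and 3.27 ± 0.34 (adjusted p = 2.4e-07). Cxcl9 rose by 3.38 ± 0.57 and 3.98 ± 0.57 and Serpina3n by 2.67 ± 0.46 and 2.81 ± 0.46. The guanylate-binding protein gene Gbp3 rose by 2.11 ± 0.39 and 2.36 ± 0.39 and the membrane transporter gene Mfsd13a by 2.97 ± 0.31 and 2.91 ± 0.31. With mLIF, Tgm2, which crosslinks proteins (2.99 ± 0.37, adjusted p = 4.6e-06), Psmb8, a subunit of the immunoproteasome (1.83 ± 0.23, adjusted p = 4.6e-06), Gbp2 (3.08 ± 0.55) and the interferon-inducible Mndal (2.82 ± 0.39) rose as well. With hOSM so did the membrane protein gene Cyb561 (2.73 ± 0.42) and Aspg (2.74 ± 0.29), an asparaginase.

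With hOSM 71 genes passed, 58 higher and 13 lower, and with mLIF 50, 46 higher and 4 lower. The culture term gave 604 (318 higher and 286 lower) and 587 (308 and 279). Under median scaling the share of calls that were higher was 96.6% in place of 81.7% for hOSM, and mLIF had 24 calls. Each of the 6 arrays lowered the hOSM count when left out, to 36, 31 and 32 for WT control replicates 1, 2 and 3 and to 41, 26 and 28 for hOSM replicates 1, 2 and 3. The mLIF count was 24 and 31 without WT control replicates 1 and 2 and 31 and 33 without mLIF replicates 2 and 3. The model of the compared groups ended the call of Cxcl9 with both ligands (adjusted p 0.094 and 0.055) and of Cyb561 with hOSM (adjusted p = 0.091).

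For the STAT3 list, 5 of 16 genes rose with both ligands (10 adjusted over the list alone with both; camera adjusted p = 1.4e-17 and 6.7e-19, 0.00018 and 0.00012 with an estimated correlation). Acute phase and complement genes had 2 and 1 risen members of 14 (camera adjusted p = 0.00015 and 0.0034, 0.0062 and 0.028 with an estimated correlation). Chemokines had 2 and 1 risen members of 17 (camera adjusted p = 6.3e-07 and 1.6e-07, 0.0062 and 0.0042 with an estimated correlation). The TGF-beta and BMP list passed with the culture term as lower (camera adjusted p = 0.028 and 0.032), but not with an estimated correlation as well (adjusted p = 0.11 and adjusted p = 0.14 with an estimated correlation). The adipocyte list did so with mLIF (camera adjusted p = 0.24, or 0.022 with the culture term and adjusted p = 0.22 with an estimated correlation as well). Tnfsf11 (2.50 ± 0.76 with hOSM, adjusted p = 0.17, and 2.17 ± 0.76 with mLIF, adjusted p = 0.33) passed with the culture term (adjusted p = 4.5e-07 and 4.4e-06) and in the model of the compared groups (adjusted p = 0.0077 and 0.019). So did Osmr (1.33 ± 0.45, adjusted p = 0.3, and 1.25 ± 0.45, adjusted p = 0.36; 0.00054 and 0.0011 with the culture term, 0.033 and 0.037 in that model). Stat3 (0.75 ± 0.23, adjusted p = 0.17, and 0.68 ± 0.23, adjusted p = 0.3) passed with the culture term (adjusted p = 0.0078 and 0.02).

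**Figure D4:**
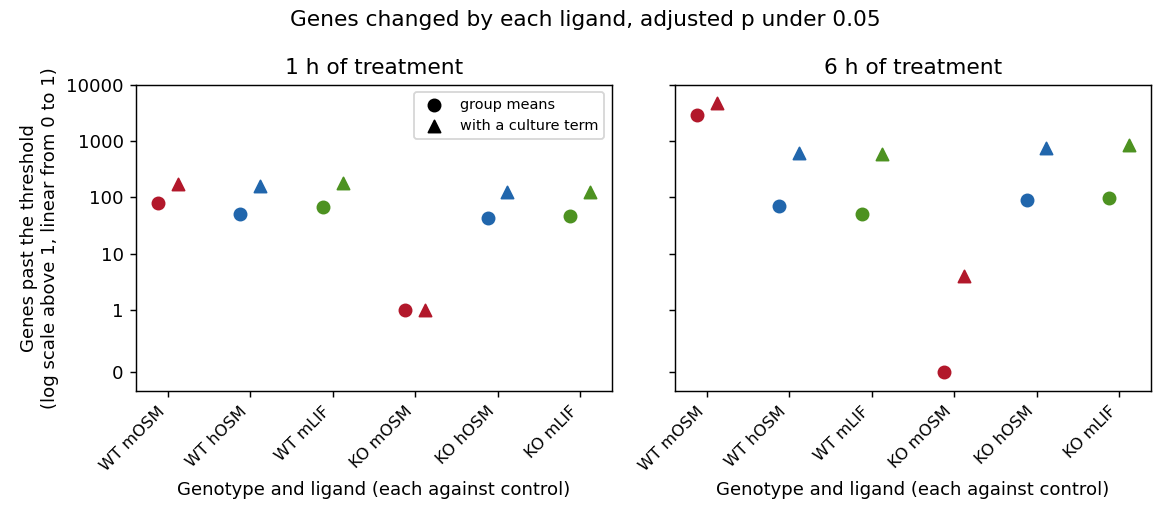
Number of genes past the threshold for each ligand against control, by genotype and time, for the group-mean model (circles) and with a culture term (triangles), on an axis that is logarithmic above 1. mOSM has 2956 genes in WT and 0 in KO at 6 h, while hOSM and mLIF have 71 and 50 in WT and 89 and 99 in KO.

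A direct comparison of the ligands asked what mOSM does beyond LIFR ligands in WT cultures. At 6 h, Ccl2 was higher with mOSM than with hOSM by 4.74 ± 0.57 (26.8-fold, adjusted p = 2.4e-07) and than with mLIF by 4.45 ± 0.57 (21.9-fold, adjusted p = 8.3e-07). Il6 was higher by 2.80 ± 0.44 (at least 4.82-fold, adjusted p = 1.9e-05) and 2.53 ± 0.44 (adjusted p = 8.2e-05), and Socs3 by 1.77 ± 0.34 and 1.70 ± 0.34. Mcoln2 was higher by 3.54 ± 0.75 and 3.53 ± 0.75, and Sema7a, a membrane-anchored semaphorin, by 3.25 ± 0.69 and 3.14 ± 0.69. Il4ra was higher than with hOSM by 3.47 ± 0.45, and Serpinb2, an inhibitor of plasminogen activators, was at least 4.18-fold higher than with mLIF. Junb was higher than with hOSM by 1.53 ± 0.42 (adjusted p = 0.0094, or 0.095 with a beadchip term). G0s2, an inhibitor of fat breakdown, was lower than with hOSM by −3.40 ± 0.53 (adjusted p = 2e-05) and than with mLIF by −3.38 ± 0.53 (adjusted p = 2.1e-05). Fam180a was lower than with mLIF by −3.07 ± 0.54 (adjusted p = 9.8e-05).

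Between mOSM and hOSM 1713 genes differed at 6 h, 722 higher and 991 lower with mOSM, and between mOSM and mLIF 1660, 694 higher and 966 lower, with 3552 (1314 and 2238) and 3385 (1314 and 2071) under the culture term. Median scaling gave a share of higher genes of 15.9% in place of 42.1% against hOSM, and 911 genes with 54.4% in place of 41.8% against mLIF. Without WT hOSM 6 h replicate 2 the first count was 1125. hOSM and mLIF themselves differed in 0 genes in limma at 1 h and 0 at 6 h (271 and 114 had an unadjusted p under 0.05, and the culture term also gave 0). The 95% interval of their difference lay inside 2-fold for 78.7% and 81.5% of the genes. At 1 h, 0 genes differed between mOSM and hOSM and 0 between mOSM and mLIF in limma (306 and 101 with an unadjusted p under 0.05), while the culture term gave 6 and 1. The count against hOSM was 1 without hOSM replicate 2 or mOSM replicate 3.

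In KO cultures, hOSM and mLIF for 1 h raised the early genes, while with mOSM Socs3 was the only gene that passed. The genes changed by both hOSM and mLIF in WT still had a mean signed difference of 0.54 ± 0.28 (SD, n = 3 cultures) under mOSM. Socs3 rose by 4.11 ± 0.34 with hOSM (adjusted p = 3.6e-10), by 4.01 ± 0.34 with mLIF (adjusted p = 4.8e-10) and by 2.52 ± 0.34 with mOSM (adjusted p = 0.00011). With hOSM and mLIF, Irf1 rose by 2.98 ± 0.25 and 2.99 ± 0.25, Socs1 by 2.70 ± 0.30 and 2.75 ± 0.30, and Cish by 2.91 ± 0.34 and 2.82 ± 0.34. Pde4b rose by 3.97 ± 0.55 and 4.43 ± 0.55, Ccl7 by 3.80 ± 0.57 and 3.78 ± 0.57 and Adamts4 by 2.26 ± 0.31 and 2.34 ± 0.31. Zfp36, which encodes a protein that destabilizes mRNA, rose by 3.03 ± 0.52 and 3.08 ± 0.52, and the phosphatase gene Dusp5 by 1.83 ± 0.28 and 1.98 ± 0.28. Under mOSM the values of Irf1 (0.80 ± 0.25), Junb (1.04 ± 0.42) and Il6 (0.80 ± 0.44) did not pass (adjusted p = 1 for each).

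With hOSM 43 genes passed, 41 higher and 2 lower, with mLIF 46, 44 higher and 2 lower, and with mOSM 1 in limma (103 had an unadjusted p under 0.05). The culture term gave 122 (104 higher and 18 lower), 124 (112 and 12) and 1. Leaving out KO hOSM replicate 1 or KO control 1 h replicate 3 gave 25 and 27 for hOSM, and KO control replicate 3 or mLIF replicate 3 gave 28 and 30 for mLIF. A model of the compared KO groups alone, whose spread includes the KO replicate 3 culture, gave 3, 6 and 0. It ended the calls of Irf1 (adjusted p 0.067 and 0.057), Ccl7, Zfp36 and Adamts4 with both ligands, of Socs1 and Dusp5 with hOSM, of Cish with mLIF and of Socs3 with mOSM (adjusted p = 0.86).

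Of 16 STAT3 targets and feedback genes, 5 rose with hOSM (10 adjusted over the list alone; camera adjusted p = 4.4e-34, 4.2e-07 with an estimated correlation). With mLIF 5 rose (9 up and 1 down adjusted over the list alone; camera adjusted p = 5.1e-31, 1.1e-06 with an estimated correlation) and with mOSM 1 (2 adjusted over the list alone; camera adjusted p = 2.5e-11, 0.0038 with an estimated correlation). Immediate early genes rose in 4, 5 and 0 of 25 cases (camera adjusted p = 3.7e-14, 1.8e-18 and 2.2e-05, with 0.00011, 1.1e-05 and 0.035 under an estimated correlation). For mOSM the list was not past the threshold with an estimated correlation and the culture term (adjusted p = 0.11). Osteoclast-regulating factors rose in 3 of 14 with both hOSM and mLIF (camera adjusted p = 2.5e-07 and 1.9e-07, 0.0013 and 0.0012 with an estimated correlation) and chemokines in 2 of 17 (camera adjusted p = 1.3e-11 and 1.1e-12, 0.00016 and 7.9e-05 with an estimated correlation). In the gp130 family list 1 of 11 rose with each (camera adjusted p = 0.0084 and 0.021, 0.0098 and 0.027 with an estimated correlation) and among matrix genes 1 of 18 (camera adjusted p = 0.01 and 0.011, 0.0098 and 0.012 with an estimated correlation). With the culture term and mOSM, the osteoblast list passed as lower (camera adjusted p = 0.062, or 4.2e-05 with it and 0.049 with an estimated correlation as well), with 0 of 11 genes past the threshold in limma. With mOSM and this term, the osteoclast-regulating list passed as higher (camera adjusted p = 0.062, or 0.011 with the term and adjusted p = 0.1 with an estimated correlation as well). Rnf213 was at least 4.04-fold higher with mLIF, and Junb rose by 2.35 ± 0.42 (adjusted p = 0.0012, or 0.27 in the model of the compared groups). Tnfsf11 (1.67 ± 0.76 with hOSM and 1.49 ± 0.76 with mLIF, adjusted p = 1 for both) passed with the culture term (adjusted p = 5e-04 and 0.0027). The heat shock list passed with both LIFR ligands (camera adjusted p = 0.016 and 0.011) but not with an estimated correlation (adjusted p = 0.36 and adjusted p = 0.3 with an estimated correlation) or with the culture term (camera adjusted p = 0.08 and 0.061). The hypoxia list, with 0 of 10 genes past the threshold in limma, passed with hOSM (camera adjusted p = 0.0043, 0.0081 with an estimated correlation, 0.0091 with the culture term and 0.027 with both). With mLIF it passed (camera adjusted p = 0.026, 0.033 with an estimated correlation) but not with the culture term (camera adjusted p = 0.07). Macrophage and osteoclast markers passed with mLIF as higher with the culture term (camera adjusted p = 0.21, or 0.028 with it and adjusted p = 0.44 with an estimated correlation as well).

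At 6 h in KO cultures, hOSM and mLIF raised Mt2, Gbp2, Casp4 and Socs3. Mt2 rose by 4.03 ± 0.64 (adjusted p = 0.00029) and 4.58 ± 0.64 (adjusted p = 3.3e-05). Gbp2 rose by 3.51 ± 0.55 and 3.59 ± 0.55, Gbp3 by 2.72 ± 0.39 and 2.91 ± 0.39, and Casp4, an inflammatory caspase, by 3.24 ± 0.46 and 3.26 ± 0.46. Socs3 rose by 3.19 ± 0.34 and 3.18 ± 0.34, Tgm2 by 3.10 ± 0.37 and 3.15 ± 0.37, Serpina3n by 3.05 ± 0.46 and 3.15 ± 0.46 and Angptl4 by 2.19 ± 0.39 and 2.11 ± 0.39. With hOSM, Psmb8 (2.06 ± 0.23, adjusted p = 4e-07) and the stress gene Gadd45g (1.37 ± 0.24) rose and Bcl3 was at least 5.07-fold higher, and with mLIF Junb rose by 2.36 ± 0.42. With mOSM, 0 genes passed in limma (201 with an unadjusted p under 0.05). Socs3 was at 1.76 ± 0.34 (adjusted p = 0.091, or 0.027 with the culture term) and Il6 at 0.07 ± 0.44 (adjusted p = 1).

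With hOSM 89 genes passed, 72 higher and 17 lower, and with mLIF 99, 78 higher and 21 lower. The culture term gave 751 (394 higher and 357 lower) and 847 (434 and 413) and, for mOSM, 4 (4 and 0), among them Socs3 and Tnfsf11 (1.47 ± 0.76, adjusted p = 0.046 with it). Under median scaling 97% of the hOSM calls were higher in place of 80.9% and 98.8% of the mLIF calls in place of 78.8%. The hOSM count was 46 without KO control 6 h replicate 3 and 47 without hOSM replicate 3. The mLIF count was 64 and 59 without control replicates 2 and 3 and 50 without mLIF replicate 3. The mOSM count was 1 without control replicate 1 and 1 without mOSM replicate 2, where Socs3 passed (2.07). A model of the compared KO groups alone gave 0 for all 3 ligands, with adjusted p of 0.079 to 0.78 for the genes named as risen with hOSM and mLIF.

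Of 16 STAT3 targets and feedback genes, 5 rose with hOSM (10 adjusted over the list alone; camera adjusted p = 1.6e-20, 5.8e-05 with an estimated correlation). With mLIF 7 rose (9 adjusted over the list alone; camera adjusted p = 2.1e-18, 0.00014 with an estimated correlation) and with mOSM 0 in limma (2 adjusted over the list alone; camera adjusted p = 1.5e-08, 0.018 with an estimated correlation). Chemokines rose in 2 of 17 with both (camera adjusted p = 1e-05 and 1.1e-06, 0.014 and 0.0065 with an estimated correlation). Acute phase genes rose in 1 of 14 with both (camera adjusted p = 0.0023 and 0.00054, 0.018 and 0.0094 with an estimated correlation). Under mOSM the chemokine and acute phase lists passed with the culture term (camera adjusted p = 0.0089 and 0.014), but not with an estimated correlation as well (adjusted p = 0.2 and adjusted p = 0.081 with an estimated correlation). The hypoxia list rose with hOSM and mLIF, with 1 of 10 genes each (camera adjusted p = 0.013 and 0.043, 0.018 and 0.047 with an estimated correlation). Under the culture term these were camera adjusted p = 0.027 and 0.067, or adjusted p = 0.076 and 0.14 with an estimated correlation as well. Matrix genes rose in 2 of 18 with mLIF (camera adjusted p = 0.043 with and without an estimated correlation, 0.075 with the culture term). With the culture term, hOSM and mLIF moved the TGF-beta and BMP list lower (camera adjusted p = 0.0089 and 0.012) and the macrophage and osteoclast markers higher (camera adjusted p = 0.013 and 6e-04). Neither passed with an estimated correlation as well (adjusted p = 0.054 and 0.073, adjusted p = 0.3 and 0.17 with an estimated correlation). Tnfsf11 (2.60 ± 0.76 and 2.61 ± 0.76, adjusted p = 0.11 for both) and Osmr (1.16 ± 0.45, adjusted p = 0.37, and 1.22 ± 0.45, adjusted p = 0.29) passed with the culture term (adjusted p = 1.7e-07 and 1.5e-07, 0.0024 and 0.0013).

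The overlap of the genotypes was counted for each ligand. Of the 45 and 41 genes that rose with hOSM at 1 h in WT and KO, 30 were shared, against 0.17 that independent lists would share, and of 61 and 44 with mLIF, 37 (0.25 from independent lists). At 6 h the shared risen genes were 47 of 58 and 72 for hOSM (0.39 from independent lists) and 37 of 46 and 78 for mLIF (0.33 from independent lists). The genotype difference of the hOSM effect passed for 0 genes in limma at 1 h and 0 at 6 h (73 and 79 with an unadjusted p under 0.05). That of mLIF passed for 0 and 0 (95 and 97), and the culture term gave 0 in all 4. The 95% intervals of these differences lay inside 2-fold for 57.1% to 59.6% of genes, or 80.3% to 82.7% with the culture term, so larger differences were not excluded for the rest.

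The mOSM effect itself differed between the genotypes. At 6 h the KO effect was lower for Ccl2 by −5.27 ± 0.81 (adjusted p = 3.2e-05, −5.13 with arrays raised to the floor) and Socs3 by −3.21 ± 0.48 (adjusted p = 2.2e-05). It was lower for Junb by −2.55 ± 0.59 (adjusted p = 0.0039) and Il6st by −2.26 ± 0.53 (adjusted p = 0.0047). The Tnfsf11 effect was lower by −3.27 ± 1.08 (adjusted p = 0.049, or 3.5e-07 with the culture term). That call ended without any of the 12 arrays except KO mOSM 6 h replicate 3, with effects of −3.44 to −2.89. It also ended with a beadchip term, median scaling or no detection filter. Il4ra (adjusted p = 1.2e-05) and Il6 (adjusted p = 0.00078) also passed as lower at 6 h, with sizes that are not fixed because of the 4 groups the WT mOSM arrays alone were above background. At 1 h the KO effect was lower for Socs1 (−2.58 ± 0.43, adjusted p = 0.0029, −2.16 with arrays raised to the floor) and Irf1 (−2.13 ± 0.35, adjusted p = 0.0029). It was lower for Rnf213 as well (adjusted p = 1.4e-05), again measured above background in WT mOSM arrays alone.

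At 6 h 1042 genes passed this test, 578 with a higher and 464 with a lower value in KO, and 2821 with the culture term (1754 and 1067). Median scaling gave 535, and without background correction 48.3% of the calls were higher in place of 55.5%. At 1 h 8 passed, 1 higher and 7 lower, and 39 with the culture term (2 and 37). Median scaling gave 4, 0 of them higher. Single arrays moved the 1 h count to 4 (without KO control replicate 1), 5 (KO control replicate 2) and 3 (each of WT mOSM replicates 1 and 3, KO mOSM replicate 2 and WT control replicate 3). The model of the compared groups gave 0 at 1 h, with adjusted p of 0.19 for Rnf213 and Irf1 and 0.68 for Socs1, and the beadchip term 0.068 for Irf1 and Socs1.

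**Figure D5:**
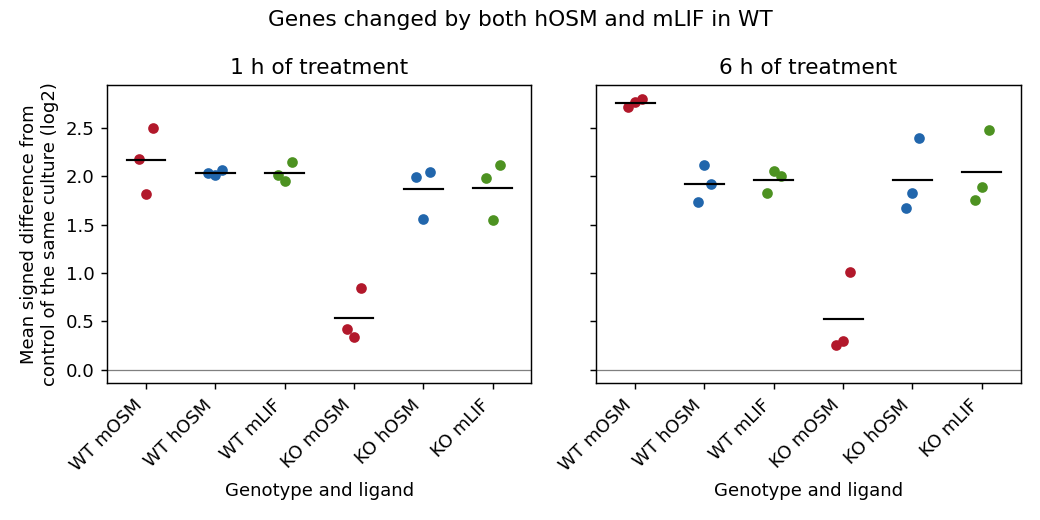
Mean signed log2 difference from the control of the same culture over the genes changed by both hOSM and mLIF in WT (46 genes at 1 h and 43 at 6 h, chosen on the WT arrays), as points for the 3 cultures and lines for their means. KO cultures average 0.54 with mOSM at 1 h and 0.52 at 6 h, against 1.86 and 1.96 with hOSM. With mOSM, KO replicate 3 is at 0.85 and 1.01 and the other KO cultures are at 0.26 to 0.42.

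Within KO cultures the ligands were also compared directly. At 1 h Irf1 was lower with mOSM than with hOSM (−2.18 ± 0.25, adjusted p = 1.5e-06) and mLIF (−2.19 ± 0.25, adjusted p = 1.3e-06), as were Socs1 (−2.43 ± 0.30 and −2.48 ± 0.30) and Rnf213 (at least 2.65-fold and 3.91-fold lower). Pde4b was lower than with mLIF (−3.28 ± 0.55, adjusted p = 0.0018). At 6 h Gbp2 (−3.22 ± 0.55, adjusted p = 0.0033, and −3.29 ± 0.55, adjusted p = 0.0017), Gbp3 (−2.53 ± 0.39 and −2.72 ± 0.39) and the interferon-inducible Mndal (−2.75 ± 0.39 and −2.88 ± 0.39) were lower with mOSM than with hOSM and mLIF. Isg15 was lower than with mLIF (−3.96 ± 0.71, adjusted p = 0.0034, or 0.055 without the KO replicate 3 culture and 0.19 with a beadchip term).

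These comparisons gave 16 and 17 genes at 1 h and 20 and 20 at 6 h against hOSM and mLIF, all lower with mOSM. Under the culture term they gave 70 (15 higher and 55 lower with mOSM), 60 (8 and 52), 179 (56 and 123) and 250 (92 and 158). hOSM and mLIF differed in 0 genes in limma at 1 h and 0 at 6 h in KO cultures (63 and 111 with an unadjusted p under 0.05, and 0 with the culture term). The intervals lay inside 2-fold for 82.4% and 82% of the genes. Single arrays lowered the counts at 1 h to 4, 3, 3 and 5 against hOSM (without mOSM replicate 1, hOSM replicate 1, mOSM replicate 2 and hOSM replicate 3). They lowered them to 7, 6, 7 and 7 against mLIF (mOSM replicate 1, mLIF replicate 1, mOSM replicate 2 and mLIF replicate 3). At 6 h they lowered them to 9, 7, 11 and 7 against hOSM (mOSM replicates 1 and 2, hOSM replicates 1 and 2) and to 13, 12 and 11 against mLIF (mOSM replicates 1 and 2, mLIF replicate 2). The model of the compared groups gave 0 and 3 at 1 h and 0 and 0 at 6 h, ending the calls named here except Rnf213 and Pde4b against mLIF.

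The controls alone showed how much changed without a ligand. Immediate early genes were lower in the 6 h than in the 1 h controls (n = 6 arrays each). Fosb fell by 4.89 ± 0.20 (adjusted p = 1.4e-19), Egr2 by 4.45 ± 0.20 (adjusted p = 3.1e-18) and Egr3 by 4.31 ± 0.32. Fos fell by 3.71 ± 0.46 (adjusted p = 1.2e-06) and Junb by 3.05 ± 0.29, and the phosphatase genes Dusp5 and Dusp1 fell by 2.77 ± 0.20 and 2.66 ± 0.32. Socs3 fell by 1.61 ± 0.24 (adjusted p = 4e-05), Id1 by 1.24 ± 0.22 and Dnajb1 by 1.40 ± 0.11. Further early genes were lower, with Errfi1 at −2.77 ± 0.24, Csrnp1 at −2.75 ± 0.28 and Gadd45g at −1.21 ± 0.17, and Egr4 was at least 3.69-fold lower. Of 25 immediate early genes, 0 rose and 16 fell (0 and 21 adjusted over the list alone; camera adjusted p = 1.5e-70, 4.1e-12 with an estimated correlation). In addition 3 of 16 STAT3 targets and feedback genes fell (5 adjusted over the list alone; camera adjusted p = 1.1e-11, 0.0018 with an estimated correlation). The heat shock and osteoclast-regulating lists passed (camera adjusted p = 0.00027 and 0.028) but not with an estimated correlation (adjusted p = 0.18 for both with an estimated correlation). The heat shock list did under the culture term (adjusted p = 0.046 with an estimated correlation). In all 145 genes passed, 65 higher and 80 lower at 6 h, with 581 under the culture term (361 higher and 220 lower). Median scaling gave 82, where 22% were higher in place of 44.8%, and without background correction 50.3% were.

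Between KO and WT controls (n = 6 arrays each, from 3 cultures each) 12 genes passed, 4 higher and 8 lower in KO. The model counts the arrays of a culture as independent, although they were alike (mean r 0.659). The SEs and adjusted p-values of this comparison are therefore likely too small. Osmr was lower by −3.08 ± 0.32 (adjusted p = 1.3e-07), and Slco2a1, a prostaglandin transporter, was higher by 1.86 ± 0.18 (adjusted p = 4.8e-08). Sema3f, a secreted semaphorin (1.24 ± 0.20, adjusted p = 0.0014), Pgm5, a cell adhesion protein related to phosphoglucomutase (−0.88 ± 0.13), and Scube2, a secreted glycoprotein (−1.15 ± 0.20), passed as well. They did not in a model of the controls alone (adjusted p 0.094, 0.12 and 0.12). The count was 7 without WT control 1 h replicate 1, 1 h replicate 2 or 6 h replicate 2. It was 4 under median scaling (without Sema3f, adjusted p = 0.065) and 83 without the KO replicate 3 culture (53 higher and 30 lower). With the culture as a random effect it was 35, which included 8 of the 12.

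Macrophage and osteoclast markers had a median difference of −2.37 between KO and WT controls, with 0 of 12 genes past the threshold (camera adjusted p = 1e-07, adjusted p = 0.34 with an estimated correlation). Adipocyte markers had a median of −0.92 (camera adjusted p = 3.2e-06, adjusted p = 0.34 with an estimated correlation). Immediate early genes had a median of −0.16 (camera adjusted p = 0.0082, adjusted p = 0.34 with an estimated correlation). Of the gp130 family list, 1 of 11 genes fell, Osmr itself (camera adjusted p = 0.005, 0.032 with an estimated correlation). The macrophage markers averaged 10.61, 8.46 and 6.41 in the 3 WT cultures and 6.41, 6.03 and 7.56 in the 3 KO cultures, so a mean over cultures of a genotype mixes unlike cultures.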

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

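Chosen after the results were seen were the splits by whole cultures, the tests of the KO replicate 3 culture and of the macrophage markers, and the tests of a wide spread between KO cultures, of the activity of the mOSM preparation and of weak signalling through LIFR. The other splits and the test of remaining OSMR signalling were set beforehand.

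The mOSM effect differed between the genotypes by a test of the difference itself for 8 genes at 1 h and 1042 at 6 h. At 1 h the KO effect was lower for Rnf213 (−3.26), Socs1 (−2.58), Irf1 (−2.13), Parp9, an ADP-ribosyltransferase family member (−1.79), and Rnd1, a small GTPase (−1.57), and higher for Id1 (2.35), which mOSM lowers in WT. Single arrays ended the Id1, Parp9 and Rnd1 calls. These were KO control replicates 1 and 2, WT control replicate 3, WT mOSM replicates 1 and 3 and KO mOSM replicate 2 for all 3 genes, KO mOSM replicate 3 for Id1 and Rnd1, and WT control replicate 2 and KO mOSM replicate 1 for Rnd1. The values without them were 2.10 to 2.37 for Id1, −1.80 to −1.65 for Parp9 and −1.65 to −1.38 for Rnd1. Rnf213, Parp9 and Rnd1 were above background in the WT mOSM arrays alone of the 4 groups, so the sizes of their differences are not fixed. At 6 h the fitted differences included Ifi205 (−5.61), Ccl2 (−5.27), Serpina3f (−5.05), Mcoln2 (−4.99), AA467197 (−4.87) and Il4ra (−4.47). Those of Ifi205, Serpina3f and Il4ra are not fixed either, because no WT control array was above background. With arrays at background raised to the floor, Ccl2, Mcoln2 and AA467197, which had 2, 2 and 1 of 3 WT control arrays above it, were at −5.13, −4.85 and −4.75 and Socs1 at 1 h at −2.16.

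Probes that the annotation leaves without a gene name were outside the comparisons. Of 2673 such probes tested, those past the threshold numbered 24 for mOSM, 10 for hOSM and 16 for mLIF in WT at 1 h, and 470, 7 and 15 at 6 h. In KO they numbered 13 for hOSM and 11 for mLIF at 1 h, and 16 and 20 at 6 h.

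The first pattern is the small response to mOSM in KO cultures. A wide spread between these cultures, with which the model of the compared groups alone gave 0 genes in place of 20 between mOSM and hOSM in KO at 6 h and 0 for each ligand, is argued against as the whole cause by the genes changed by both hOSM and mLIF in WT, whose mean change was lower with mOSM than with hOSM by −1.44 ± 0.08 (SD, n = 3 cultures) within the KO cultures. An mOSM preparation without activity is argued against by the 2956 genes it changed in WT at 6 h, although the labels do not say that the same preparation was used. Weak signalling of mOSM through LIFR may account for what remained. The genes changed by both hOSM and mLIF in WT averaged 0.52 ± 0.42 (SD, n = 3 cultures) under mOSM in KO at 6 h. They were at 1.01 in KO replicate 3 and at 0.26 and 0.30 in KO replicates 1 and 2. The mean was above the 0.088 that 99% of 10000 random lists stayed under. Those lists were matched on mean expression, and their genes need not vary together as genes of 1 response do. The limit of 0.088 may thus be too narrow, and it does not exclude chance. Remaining signalling through OSMR cannot be told apart from weak signalling through LIFR. The test took 1324 genes that passed with mOSM in WT at 6 h and with neither hOSM nor mLIF. They also differed between mOSM and hOSM and between mOSM and mLIF. They kept a share of 0.081 of their WT response in KO. They were chosen on the WT arrays that give that response, so the share may be biased low. It was under a bound of 0.094, but by less than the spread of the cultures (0.041 to 0.122 at 1 SD). The rule for the bound was set beforehand. Its value came from the share of 0.188 kept by the genes changed by both hOSM and mLIF, whose own spread that range leaves out. The set does not isolate OSMR, because hOSM and mLIF moved it as well. In KO cultures it averaged 0.29 ± 0.12 with hOSM, 0.30 ± 0.07 with mLIF and 0.10 ± 0.05 with mOSM (SD, n = 3 cultures).

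The second pattern is the KO replicate 3 culture, in which 332 genes were over 1 log2 above and 275 below all other cultures, on arrays spread over 6 beadchips. Its thaw day is argued against as the cause by the correlation over genes of −0.084 between the replicate 3 deviations in KO and WT. A minority of other cells added to the culture is argued against by 228 genes that were detected on all other arrays and over 1 log2 lower here. Cells of another skeletal site may be the source, as 46.2% of 13 Hox genes, against 5.7% of all genes, lay over 1 log2 outside the range of the other cultures. That is a hypothesis, and no label gives another site.

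The third pattern is the spread of macrophage markers between cultures. Over the 6 cultures the markers had a mean r of 0.922 with each other, the lowest being 0.544, so a differing share of macrophages between cultures is a candidate explanation. One of them, Lyz2, was at 14.24 in WT replicate 1. Genotype and culture cannot be told apart here, since the exact two-sided permutation test of the KO and WT culture means gave p = 0.3 (difference −1.83) with 3 cultures each.

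For comparisons of 3 with 3 arrays the 10 splits are too few for a share under 0.05. For ligand against control, 1 of 10 splits gave as many genes as the real one, which had 80, 50 and 67 (WT, 1 h, in the order mOSM, hOSM, mLIF), 2956, 71 and 50 (WT, 6 h), 1, 43 and 46 (KO, 1 h) and 89 and 99 (KO, 6 h, hOSM and mLIF), and the highest other gave 0 each time. For mOSM in KO at 6 h, with 0 genes, 10 of 10 did and the highest other gave 2. Between mOSM and hOSM or mLIF, 1 of 10 did at 6 h in WT (1713 and 1660, highest other 1 and 1) and in KO at 1 h (16 and 17, highest other 2 and 0) and 6 h (20 and 20, highest other 0 and 3). For those at 1 h in WT, with 0 genes each, 10 of 10 did, with 1 and 2 as the highest other. Between hOSM and mLIF, with 0 genes each, 10 of 10 did, with highest others of 0, 0, 1 and 3 for WT 1 h, WT 6 h, KO 1 h and KO 6 h. Where the real count was 0, every split reaches it, so these shares were fixed in advance.

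For the genotype difference of the mOSM effect, 9 of 100 splits of the arrays gave at least 8 genes at 1 h (highest other 96). At 6 h, 8 of 100 gave at least 1042 (highest other 1755). The other splits that did so all left the mOSM arrays of each genotype together and mixed only the controls. Such splits still set the KO against the WT mOSM arrays and so keep the real difference between them. These shares therefore cannot decide on chance, which is not excluded. Splits that mixed the mOSM arrays gave at most 0 at 1 h and 1 at 6 h. With whole cultures exchanged, 1 of 10 splits did at each time, with 0 as the highest other, and 10 splits are too few for a share under 0.05. For hOSM and mLIF, with 0 genes each, 100 of 100 did, the highest others being 1 and 20 at 1 h and 3 and 2 at 6 h. Every split reaches a count of 0, so this share was fixed in advance and says nothing on chance. The same holds for whole cultures, which gave 10 of 10 and 0 as the highest other for both.

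For KO against WT controls, 1 of 100 splits reached the 12 genes (highest other 1). The arrays of a culture are not independent, and of the 10 splits of whole cultures 1 did (highest other 4), too few for a share under 0.05. For 6 h against 1 h controls, 1 of 100 splits reached 145 genes (highest other 42), and of 32 splits within cultures 1 did (highest other 19). Both shares are under 0.05, which argues against chance. The share of 0.03 is the smallest that 32 splits allow, so chance is not excluded.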

How the results depend on the processing

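The culture term, the culture as a random effect, the fit without the KO replicate 3 culture and the first thaw day alone were chosen after the data were examined. In some settings the larger part of the calls had the other direction. These were mOSM against mLIF in WT at 6 h under median scaling (496 higher and 415 lower), the mOSM interaction at 6 h without background correction (48.3% higher in place of 55.5%), and the genotype controls without the KO replicate 3 culture (53 and 30). The time controls did so with a replicate block (132 and 109), the culture term (361 and 220) and without background correction (79 and 78). With the deposited values and without the detection filter (19057 genes) all 32 counts were within 1.5 times. Other counts moved as follows, and the cause was not tested except that fewer arrays were used where arrays were left out. Arrays are named as in the text, a lone array was assumed to vary like the others, and probes near background limit the genes that can be measured.

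With a replicate block the counts were, in WT, 85 (hOSM, 1 h), 104 (mLIF, 1 h), 173 (hOSM, 6 h) and 155 (mLIF, 6 h), in KO 70, 70, 225 and 233, for the mOSM interaction 22 and 1611, for mOSM against hOSM and mLIF in KO 37 and 33 (1 h) and 45 and 61 (6 h), and for the genotype and time controls 161 and 241. With a beadchip block they were 30 (WT mOSM, 1 h), 16 (WT mLIF, 1 h), 42 (WT hOSM, 6 h), 20 (KO hOSM, 1 h), 59 and 46 (KO hOSM and mLIF, 6 h), 3 (interaction, 1 h), 10 and 11 (mOSM against hOSM and mLIF, KO, 1 h), 10 and 10 (6 h), 7 and 92 (controls). No background correction gave 13 (interaction, 1 h) and 2 (mOSM against hOSM, WT, 1 h). Median scaling gave 24 (WT mLIF, 6 h), 4 and 535 (interaction), 911 (mOSM against mLIF, WT, 6 h), 4 and 82 (controls).

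The compared groups alone gave 41 and 40 (WT mOSM and mLIF, 1 h), 0, 3 and 6 (KO mOSM, hOSM and mLIF, 1 h), 0 and 0 (KO hOSM and mLIF, 6 h), 0 (interaction, 1 h), 0 and 3 (mOSM against hOSM and mLIF, KO, 1 h), 0 and 0 (6 h) and 2 (genotype controls). The culture term gave 176, 156 and 182 (WT, 1 h), 4858, 604 and 587 (WT, 6 h), 122 and 124 (KO hOSM and mLIF, 1 h), 4, 751 and 847 (KO, 6 h), 39 and 2821 (interaction), 6 and 1 (mOSM against hOSM and mLIF, WT, 1 h), 3552 and 3385 (WT, 6 h), 70 and 60 (KO, 1 h), 179 and 250 (KO, 6 h) and 581 (time controls). The random culture gave 35 (genotype controls). Without the KO replicate 3 culture the counts were 30 (interaction, 1 h), 30 and 33 (mOSM against hOSM and mLIF, KO, 1 h) and 83 (genotype controls). The first thaw day alone gave 86 (WT hOSM, 1 h), 121 and 131 (WT hOSM and mLIF, 6 h), 75 (KO hOSM, 1 h), 19 (interaction, 1 h), 1 (mOSM against hOSM, WT, 1 h), 43 and 38 (KO, 1 h), 49 and 56 (KO, 6 h) and 130 (genotype controls).

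Leaving out one array gave ranges of 46 to 86 (WT mOSM, 1 h), 32 to 41 (hOSM), 32 to 55 (mLIF), 26 to 41 (WT hOSM, 6 h), 24 to 38 (mLIF), 25 to 54 (KO hOSM, 1 h), 28 to 50 (mLIF), 0 to 1 (KO mOSM, 6 h), 46 to 100 (hOSM), 50 to 95 (mLIF), 3 to 12 (interaction, 1 h), 0 to 1 (mOSM against hOSM, WT, 1 h), 1125 to 1667 (6 h), 3 to 14 (KO, 1 h), 7 to 15 (KO, 6 h), 6 to 18 (mOSM against mLIF, KO, 1 h), 11 to 29 (KO, 6 h) and 7 to 14 (genotype controls). Of the named gene tests, 14 lost their call with a beadchip block and 65 in the compared groups alone, and 13 gained one with a replicate block.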

Other observations

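The values here were looked up after the results were seen. The Hox genes named are those counted in the test of another skeletal site, and the other values serve no test. In the KO replicate 3 culture, 6 of 10 chondrocyte markers were over 1 log2 above the other KO cultures and 1 was below, Comp, a cartilage matrix protein gene, at 10.06 against 12.99 and 13.66. The list was also high in WT replicate 2, with a mean of 8.88 against 9.62 in KO replicate 3 and 7.18 to 7.42 in the other cultures, so it does not set KO replicate 3 apart from all of them. Among the Hox genes, which mark position along the body axis, Hoxa2, Hoxa5 and Hoxa7 were higher than in every other culture and Hoxb2, Hoxb4 and Hoxd8 lower. The adipocyte genes Adipoq and Lpl were at 4.65 and 9.66 there, against 10.61 to 12.83 and 13.24 to 14.17 in the other cultures. The highest Osmr signal of any KO array, 8.75, belonged to this culture.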
